A study of Mus musculus with 8 samples.

How the data were processed

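RNA of 8 cultures or fractions of the mouse lines MBA-15 and DA3 was hybridised to Affymetrix MoGene ST arrays, 2 arrays in each of 4 groups: MBA-15 co-culture, MBA-15 alone, DA3 alone and DA3 co-culture. The group and the replicate number came from the sample titles, and an assay number (3, 4 or 5), whose meaning is not given in the sources used here, came from the sample descriptions. Assay 4 holds 1 array each of MBA-15 co-culture, MBA-15 alone and DA3 alone, assay 3 holds 1 array of each of the 4 groups, and assay 5 holds 1 DA3 co-culture array. The deposited values are log2 expression per probe set, made with RMA (background correction, normalization between arrays and summary of probes) and Partek 6.5 per the submitters' processing notes, with no parameters given. That the deposited values are on a log2 scale was read from their range and from the RMA named in the notes. All 8 columns of the table were used, and the normalization between arrays means that a change is relative to the other genes of the array. Array medians lay between 4.479 and 4.642, and no 2 arrays shared more than 2 identical values.

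Of 35556 probe sets, 21789 had exactly 1 gene symbol in the platform annotation, 1621 had several and 12146 were not listed there and are unnamed here. Through the Entrez identifier 21698 of the 21789 were found in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols changed. Of several probe sets of a gene, which 999 genes had, the one with the highest mean over all arrays was kept, which left 19938 genes, with no filter on dim ones. No genome coordinates are given.

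Each comparison was a contrast of 4 group means fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 4 groups share 1 estimate of the spread with 4 residual and 2.6 prior degrees of freedom. P-values were adjusted over all genes after Benjamini and Hochberg, two-sided, at a threshold of 0.05. Errors given with a change are standard errors from limma, and errors given with a level are standard deviations over 2 arrays. The comparisons, the tests, the rule for named genes, the 22 gene lists and most of the other settings tried were fixed before the data were examined. The named genes are the 10 largest rises and the 10 largest falls past the threshold whose arrays do not overlap between the groups, filled up to 5 with the largest changes that did not pass. For the difference between the lines they are the 5 largest in each direction, in each list up to 4 members with the largest absolute change, and always Epcam. Predicted and clone-named loci were passed over. Other genes were chosen after their values were seen, among them the Y-linked Eif2s3y, Uty and Kdm5d, Cldn7 in the plot of line genes, and the members named because they passed.

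Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 22 lists of a comparison. With a correlation estimated from the residuals, 0 of the 9 lists called for MBA-15, 0 of the 11 for DA3, 1 of the 12 between the lines alone and 0 of the 9 for the difference still passed. The lists cover interferon response, chemokines and cytokines, osteoblast differentiation, extracellular matrix, matrix proteases, epithelial and stromal markers, regulators of epithelial-mesenchymal transition, cell cycle, TGF-beta, NF-kB and p53 targets, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, immediate early genes, Wnt and Notch signalling, adhesion, and markers of leukocytes, endothelium, fat, and muscle and cartilage.

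After the data were examined, shares of RNA were estimated on the linear scale from genes over 4 log2 units apart between MBA-15 co-culture and DA3 alone. The higher DA3 share came from the genes high in DA3 and the lower share from the genes high in MBA-15. The tests at the lower share were added after the results at the higher share were known. For the matched comparisons, mean DA3 alone values were mixed into each MBA-15 co-culture array at the share of the array of the same replicate number labelled MBA-15 alone, or at the lower share that the genes restricted to MBA-15 leave, and mean MBA-15 co-culture values were mixed into the DA3 alone arrays at the mean share of the DA3 co-culture arrays. The removal of the median change of each twentieth of expression from the list means was also chosen after the data were examined. In a trial of the mixing at the DA3 share with changes planted in 200 genes high in MBA-15 co-culture and low in DA3 alone, 0 of 200 genes with a change of 1 log2 unit and 55 of 200 with a change of 2 were called, and 0 and 48 at the lower share.

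The fit was tested on simulated data over 19938 genes, with 50 genes changed at each of 4 sizes. The variances were drawn from the prior that limma fitted to the real arrays, with independent normal noise and the same variance in all groups. On the real arrays the difference between replicates had an SD of 0.251 in DA3 alone and 0.482 in DA3 co-culture. The numbers of this trial therefore hold for the model and may not carry over to these data. For MBA-15 co-culture, 19, 43, 45 and 50 of 50 genes changed by 1, 2, 3 and 4 log2 units were called, with 11 false calls. For DA3 co-culture the numbers were 19, 38, 47 and 50 with 11 false calls, and for the lines alone 16, 43, 49 and 47 with 8. Other settings, chosen before the data were examined, were the replicate or the assay number as a block, the assay number as a random block, only the 4 arrays compared, a repeat of quantile normalization, median centring, a filter on dim genes, an intensity trend in eBayes, the mean over the probe sets of a gene, a minimum fold, an estimated correlation and leaving out each array in turn. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.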

Results

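Gene expression was measured on 8 mouse Affymetrix MoGene ST arrays that fall into 4 groups of 2. The stromal line MBA-15 has a pre-osteoblastic character and the line DA3 derives from a mammary adenocarcinoma, and each was grown alone or in co-culture with the other. The cells were then parted with magnetic particles against EpCAM (CD326), a surface glycoprotein of epithelial cells, into a DA3 fraction that carries it and an MBA-15 fraction that does not. The study asked how bone stromal and breast carcinoma cells affect each other. All 8 sample descriptions name 24 h, while the growth protocol names 24 or 48 h. The array medians lay between 4.479 and 4.642 on the log2 scale, and 19938 genes were compared. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

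Epcam, the gene used for the separation, went against the label of the arrays named MBA-15 alone. Its log2 level was 8.45 and 9.25 on the 2 arrays labelled MBA-15 alone, 5.58 and 5.19 in MBA-15 co-culture, 9.57 and 9.46 in DA3 alone, and 9.30 and 9.38 in DA3 co-culture. The 32 measured epithelial markers followed it, with array means of 6.57 and 7.06 on the arrays labelled MBA-15 alone against 4.59 and 4.56 in MBA-15 co-culture and 7.73 and 7.64 in DA3 alone. The Y-linked gene Eif2s3y, which stayed at 3.73 and 3.76 in DA3 alone, was at 6.70 and 6.16 on the arrays labelled MBA-15 alone and at 7.22 and 7.15 in MBA-15 co-culture. On a linear scale running from the mean of MBA-15 co-culture to the mean of DA3 alone, 26 genes restricted to DA3 stood at a median of 41.2% (quartiles 36.3 and 45.3%) on array 1 labelled MBA-15 alone. On array 2 the median was 61.0% (57.0 and 68.2%). In the same way, 41 genes restricted to MBA-15 stood at 5.4% and 5.1% of their MBA-15 co-culture level on the DA3 co-culture arrays, on a scale whose zero is the mean of DA3 alone. The DA3-restricted genes stood at 65.5% (quartiles 35.9 and 84.5%) and 78.1% (52.3 and 95.8%) of their DA3 alone level on the DA3 co-culture arrays. The MBA-15-restricted genes stood at 77.4% and 53.1% on the arrays labelled MBA-15 alone, so the shares of each of these arrays add up to more than 100%. These genes were chosen after the data were examined, as those over 4 log2 units apart between MBA-15 co-culture and DA3 alone. The descriptions of all 4 arrays labelled alone carry the word mix beside the fraction and do not say what was mixed. The MBA-15 samples are therefore called the arrays labelled MBA-15 alone. The word also stands on the DA3 alone arrays, which are the control for DA3 co-culture and the DA3 end of the shares, so DA3 alone is a label too.

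**Figure D1:**
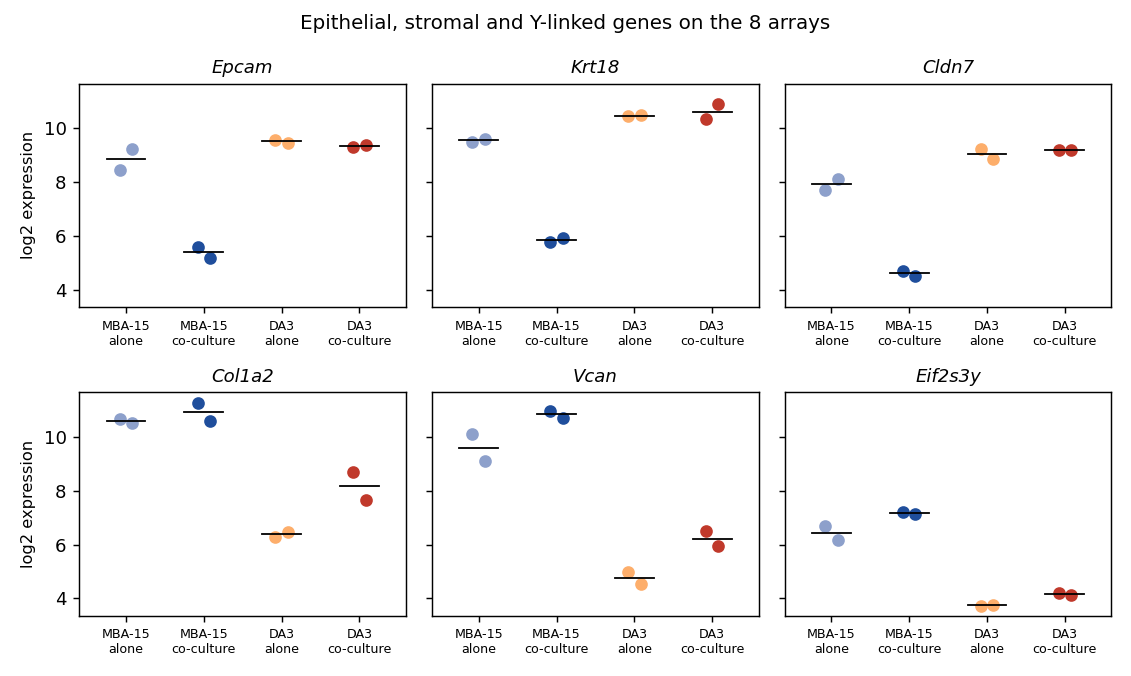
Log2 expression of 6 genes on the 8 arrays, with a point for each array and a line at the mean of each group of 2. On this log2 scale Epcam, Krt18 and Cldn7 lie nearer to DA3 than to MBA-15 co-culture on the arrays labelled MBA-15 alone (Epcam mean 8.85 against 9.52 and 5.39), while Col1a2, Vcan and the Y-linked Eif2s3y lie nearer to MBA-15 co-culture. A mixture can lie nearer to the higher of its sources on a log2 scale, so nearness here does not measure a share.

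The first comparison set MBA-15 cells from co-culture against the arrays labelled MBA-15 alone, to ask what contact with carcinoma cells changes in the stromal line. Genes of epithelial cells were far lower in MBA-15 co-culture. Krt7, an epithelial keratin, fell by 4.27 ± 0.16 log2 units (SE, adjusted p = 0.000981, limma with Benjamini-Hochberg adjustment), from 9.15 ± 0.11 to 4.88 ± 0.00 (SD, n = 2 arrays per group). The adhesion molecule Mpzl2 fell by 4.31 ± 0.20, the keratin Krt18 by 3.71 ± 0.19 and the epithelial splicing regulator Esrp1 by 3.62 ± 0.41. Epcam fell by 3.46 ± 0.27. Among the genes that passed, the rises were smaller, led by Thsd7a at 1.41 ± 0.14, and they included the transcriptional repressors of epithelial genes Zeb2 at 1.20 ± 0.15 and Zeb1 at 0.98 ± 0.12.

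In all, 15 genes rose and 154 fell at an adjusted p under 0.05 in limma, and 1954 genes had an unadjusted p under 0.05. Besides those named, the largest falls that passed were Bst1 (-4.23), the small GTPase gene Rab25 (-3.67), Tc2n (-3.66), S100a14 (-3.64), the laminin gene Lama5 (-3.61) and the peroxisomal oxidase gene Acox2 (-3.56). The largest rises that passed were, after Thsd7a, Prex2 (1.24), the potassium channel gene Kcnj2 (1.18), Dock11 (1.16), Zswim6 (1.15), the receptor gene Calcrl (1.08), Zfp365 (1.03) and Sfmbt2 (1.01). All 154 genes that fell were more than 1 log2 unit higher in DA3 alone than in MBA-15 co-culture, and all 15 that rose were more than 1 log2 unit lower there, a comparison that shares the co-culture arrays. Read on a co-culture array left out of the fit, this held for 74 of 92 lower and 13 of 16 higher calls with array 1 left out and for 13 of 13 lower calls with array 2 left out. Of all genes 5.7% and 9.1% lay on the first side of array 1 and array 2, and 6.3% on the other side of each. The change of Epcam was -4.06 within assay number 3 and -2.87 within assay number 4, and that of Krt18 was -3.69 and -3.72. With the assay number as a block, 5 genes rose and 177 fell, and 131 of the 169 genes called without it were among them. Fewer genes were called when MBA-15 co-culture array 1 or 2, array 2 labelled MBA-15 alone, or DA3 alone array 1 or 2 was left out. Some of those calls, without MBA-15 co-culture array 1 above all, were not among the 169. When the DA3 share of the arrays labelled MBA-15 alone was mixed into the co-culture arrays, a step chosen after the data were examined, limma called 0 of the 169 genes and 269 genes had an unadjusted p under 0.05. The median absolute change of the 169 went from 2.06 to 0.14. The share was estimated from genes high in DA3, so their smaller change holds in part by construction.

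**Figure D2:**
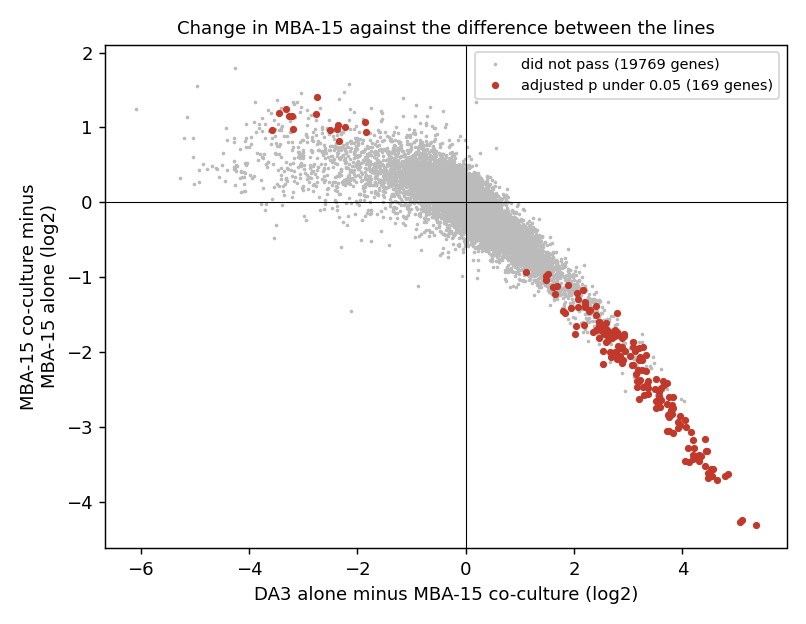
Change of each of 19938 genes between MBA-15 co-culture and the arrays labelled MBA-15 alone (vertical, log2) against the difference between DA3 alone and MBA-15 co-culture (horizontal, log2), with the 169 genes past an adjusted p of 0.05 in red. Both axes share the MBA-15 co-culture arrays, which alone gives a downward slope; the 154 genes that fell all lie beyond 1 on the right and the 15 that rose all lie beyond -1 on the left.

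Among 22 gene lists fixed before the data were examined, the epithelial markers fell as a group in MBA-15 co-culture. Of 32 measured markers, 19 fell (28 adjusted over the list alone), and the mean change was -2.24 (camera adjusted p = 7.84e-48, and adjusted p = 0.22 with an estimated correlation). The mean was -2.50 within assay 3 and -1.98 within assay 4. Of 16 regulators of epithelial-mesenchymal transition, Zeb1 and Zeb2 rose (3 genes adjusted over the list alone), and the list rose by a mean of 0.281 (camera adjusted p = 0.0123, and adjusted p = 0.534 with an estimated correlation). The interferon response genes rose by a mean of 0.389 (camera adjusted p = 0.00102, and adjusted p = 0.69 with an estimated correlation) with 0 of 32 members passing, over all genes or adjusted over the list alone. Samd9l had a value of 1.20 ± 0.44 and Oas2 of 1.00 ± 0.41. The interferon mean was -0.046 without MBA-15 co-culture array 1 and -0.077 without array 2 labelled MBA-15 alone. The extracellular matrix list (mean 0.257, camera adjusted p = 0.0269), the stromal markers (0.18, 0.0123) and the osteoblast genes (0.157, 0.0269) also rose with 0 of 30, 32 and 23 members passing either way. With an estimated correlation their adjusted p was 0.534, 0.337 and 0.534. Within assay 3 and assay 4 the mean was 0.041 and 0.474 for the matrix list, 0.044 and 0.519 for the transition regulators, 0.148 and 0.211 for the stromal markers, 0.106 and 0.209 for the osteoblast genes, and 0.42 and 0.358 for the interferon list. Vcan, the proteoglycan versican, had a value of 1.25 ± 0.36 and Col5a2 of 0.99 ± 0.20, and neither passed.

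The cell cycle list fell by a mean of 0.238 in MBA-15 co-culture (camera adjusted p = 0.000925, and adjusted p = 0.282 with an estimated correlation), and the mitotic kinase gene Aurka (-1.11 ± 0.12) was the 1 of 38 members to pass, over all genes and adjusted over the list alone. The unfolded protein response list (mean -0.306, camera adjusted p = 0.000135) and the TGF-beta targets (-0.345, 0.0269) fell with 0 of 21 and 17 members passing (0 and 2 adjusted over the list alone). With an estimated correlation their adjusted p was 0.434 and 0.534, and the TGF-beta mean was 0.033 without MBA-15 co-culture array 2. Within assay 3 and assay 4 the mean was -0.666 and -0.025 for the TGF-beta targets, -0.438 and -0.174 for the unfolded protein response, and -0.25 and -0.226 for the cell cycle. Of the chemokines and cytokines, the list did not pass (mean -0.263, camera adjusted p = 0.136), but Cxcl16 (-2.46), Ccl20 (-2.06) and the cytokine gene Lif (-1.43) fell, 3 of 28 members (4 adjusted over the list alone). Single members of other lists that did not pass also fell: Perp (-2.14) among 18 p53 targets, Wnt7b (-2.57) among 28 Wnt and Notch genes, Itgb6 (-1.50) among 27 adhesion genes and Tnnt2 (-1.21) among 15 muscle and cartilage markers. Adjusted over the list alone, 2 p53 targets and 1 adhesion gene were higher, and 2, 1, 5 and 1 genes of these 4 lists were lower. The means of these lists were -0.097, -0.094, -0.212 and -0.047, with camera adjusted p = 0.588, 0.782, 0.196 and 0.573. Matrix proteases (0.02), NF-kB targets (-0.286), hypoxia and glycolysis (-0.088), cholesterol synthesis (-0.107), immediate early genes (-0.203) and the leukocyte (0.05), endothelial (0.009) and adipocyte (0.102) markers did not pass, with camera adjusted p = 0.346, 0.136, 0.559, 0.346, 0.107, 0.287, 0.359 and 0.196. In these 8 lists 0 members passed, and adjusted over the list alone 1 endothelial marker was lower and 0 genes of the other 7 passed. The mean and the median differed in sign for the chemokine, p53, Wnt and Notch, adhesion, and muscle and cartilage lists. After removal of the median change of each twentieth of expression, the mean was -0.135 for the cell cycle list, lower than in all but 15.6% of 10000 random lists of like expression, -0.209 for the unfolded protein response (8%) and -0.265 for the TGF-beta targets (6.2%). The chemokines (-0.246, 1.7%) and NF-kB targets (-0.247, 3.7%), which did not pass camera, lay lower among such random lists than these. This mean was -2.179 for the epithelial markers, 0.458 for the interferon list, 0.372 for the transition regulators, 0.304 for the matrix list, 0.206 for the stromal markers and 0.115 for the osteoblast genes. With the DA3 share matched, the mean was -0.363 for the interferon list, -0.223 for the matrix list, -0.187 for the stromal markers, -0.275 for the transition regulators and -0.066 for the osteoblast genes, all of them called higher as deposited. It was 0.109 for the epithelial markers, 0.01 for the cell cycle, -0.117 for the TGF-beta targets and -0.142 for the unfolded protein response. The osteoblast, epithelial and cell cycle lists were no longer called (camera adjusted p = 0.781, 0.379 and 0.32). Camera called 13 lists there, or 0 with an estimated correlation. At the lower shares of 22.6% and 46.9% that the MBA-15-restricted genes leave, the interferon, matrix, stromal, transition and osteoblast means were -0.074, -0.035, -0.038, -0.057 and 0.02 and were not called (camera adjusted p = 0.185, 0.185, 0.494, 0.814 and 0.359). The epithelial and cell cycle means were -0.309 and -0.054 and were called (2.06e-08 and 0.0108). Camera then called 9 lists, or 0 with an estimated correlation. The means of lists high in MBA-15 thus depend on the share mixed in.

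The second comparison set DA3 cells from co-culture against the arrays labelled DA3 alone, to ask what contact with stromal cells changes in the carcinoma line. Itga2, which encodes an alpha subunit of a collagen-binding integrin, rose by 3.89 ± 0.36 log2 units, from 4.14 ± 0.17 to 8.03 ± 0.64 (SD, n = 2; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0468). The carboxypeptidase gene Cpa4 rose by 2.51 ± 0.13, from 3.89 ± 0.04 to 6.40 ± 0.13 (limma, adjusted p = 0.0077). Stra6, a membrane receptor for retinol-binding protein, fell by 3.64 ± 0.28, as did Asb2, a substrate adaptor of a ubiquitin ligase (-2.86 ± 0.22). The endothelin gene Edn1 (-2.56 ± 0.22) and the chemokine gene Ccl20 (-2.24 ± 0.16) fell too. The lower of the levels compared lies below the lowest array median of 4.479 for Itga2, Cpa4, Stra6, Edn1 and Ccl20, so these differences are at best lower bounds.

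These 2 genes rose and 6 fell in limma, the other falls being Pla1a (-1.75 ± 0.16) and Atp6v0e2 (-1.69 ± 0.15), and 2973 genes had an unadjusted p under 0.05. Serpinb2, an inhibitor of plasminogen activators, was at 9.29 in co-culture against 5.53 alone and did not pass (3.76 ± 0.37, adjusted p = 0.0544), nor did Prl2c5 of the proliferin family (3.25 ± 0.42, adjusted p = 0.0836) and the uridine phosphorylase gene Upp1 (2.88 ± 0.51, adjusted p = 0.138). The proliferin genes are close copies, so the probe set of Prl2c5 may read its relatives too. Upp1 was at 4.02 in DA3 alone, below the lowest array median of 4.479, so its difference is at best a lower bound. Epcam differed by -0.18 ± 0.27 (limma, adjusted p = 0.744). Within assay number 3, the only one that holds both groups, the change was 4.47 for Itga2, 2.64 for Cpa4, -4.07 for Stra6 and -2.11 for Ccl20. Assay 5 holds only 1 DA3 co-culture array, so a block on the assay number leaves this contrast with the other co-culture array. With the assay number as a block 0 genes rose and 0 fell, and leaving out any 1 of the 8 arrays left between 0 and 3 called genes. With MBA-15 RNA mixed into the DA3 alone arrays at the estimated share of 5.25%, a step chosen after the data were examined, 5 of the 8 calls remained, and Itga2 (3.86, adjusted p = 0.0547), Pla1a (-1.72, 0.0544) and Atp6v0e2 (-1.62, 0.0547) missed the threshold.

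**Figure D3:**
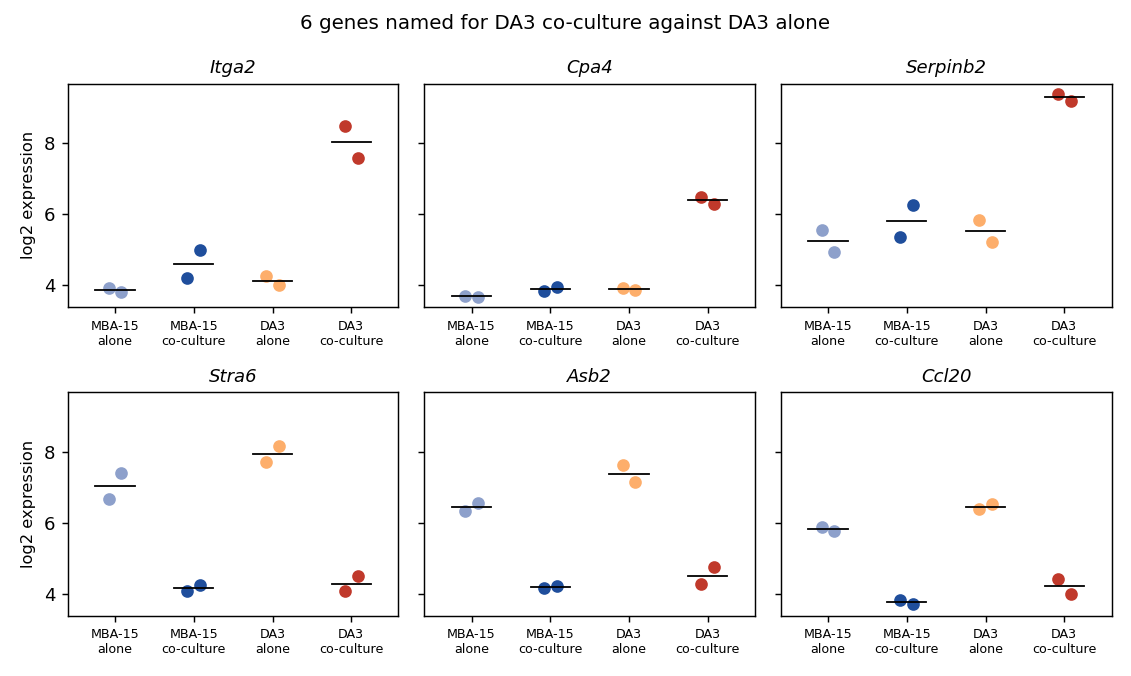
Log2 expression of Itga2, Cpa4, Serpinb2, Stra6, Asb2 and Ccl20 on the 8 arrays, with a point for each array and a line at the mean of each group of 2. Itga2 and Cpa4 passed the test as higher in DA3 co-culture than in DA3 alone (means 8.03 and 6.40 against 4.14 and 3.89), Serpinb2 did not pass, and Stra6, Asb2 and Ccl20 passed as lower.

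Stromal and matrix genes rose as groups in DA3 co-culture, beside the 5.4% and 5.1% of MBA-15-restricted expression on these arrays. The 32 stromal markers rose by a mean of 0.35 (camera adjusted p = 0.00254, and adjusted p = 0.277 with an estimated correlation), with 0 members passing (5 higher and 1 lower adjusted over the list alone) and values of 1.65 ± 0.23 for Vim and 1.45 ± 0.20 for Fstl1. The extracellular matrix list rose by 0.312 and the osteoblast list by 0.32 (camera adjusted p = 0.00355 for both, and adjusted p = 0.358 for both with an estimated correlation). Their members included the collagen genes Col1a1 (1.92 ± 0.60) and Col1a2 (1.81 ± 0.36) and, at -2.12 ± 0.33, Col12a1, and 0 of 30 and 0 of 23 passed (4 higher and 3 lower, and 1 higher, adjusted over the list alone). With the MBA-15 share matched, the stromal markers (mean 0.065, camera adjusted p = 0.394) and the matrix list (-0.073, 0.617) lost their call. The osteoblast list kept it (0.198, 0.0251), but had an adjusted p of 0.484 there with an estimated correlation. The share was set on genes high in MBA-15, which members of these lists can be. The loss of the calls may thus hold in part by construction. Matrix proteases and their inhibitors rose by 0.281 (camera adjusted p = 0.0289, and adjusted p = 0.358 with an estimated correlation), with values of 2.31 ± 0.35 for Mmp10 and -2.60 ± 0.37 for Timp3, and 0 of 24 passed (6 higher and 1 lower adjusted over the list alone). Markers of muscle and cartilage (0.238, camera adjusted p = 0.00366), leukocytes (0.173, 0.0247) and adipocytes (0.229, 0.0398) rose too, with 0 members passing over all genes or adjusted over the list alone. With an estimated correlation their adjusted p was 0.358, 0.579 and 0.358. Their mean levels in DA3 alone and DA3 co-culture were 4.73 and 4.97, 3.95 and 4.12, and 4.14 and 4.37. These lie near or below the array medians of 4.479 to 4.642. Dim genes rose in general, by medians of 0.109 to 0.176 in the first to the tenth twentieth of expression. With the MBA-15 share matched, the proteases (mean 0.15, camera adjusted p = 0.291) and adipocyte markers (0.182, 0.0833) lost their call. The muscle and cartilage (0.24, 0.00402) and leukocyte (0.146, 0.0366) markers kept it, but had adjusted p = 0.484 and 0.825 there with an estimated correlation. After removal of the median change of each twentieth of expression, the mean was 0.212 for the muscle and cartilage markers, 0.082 for the leukocyte markers, 0.154 for the adipocyte markers, 0.443 for the stromal markers, 0.447 for the matrix list, 0.249 for the osteoblast genes and 0.407 for the proteases, at percentiles 99.3, 95.3, 98.6, 100, 100, 100 and 100 of 10000 random lists of like expression.

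The cell cycle list fell in DA3 co-culture, lower in 36 of 38 genes (mean -0.361, camera adjusted p = 6.1e-06, and adjusted p = 0.213 with an estimated correlation). None passed singly, over all genes or adjusted over the list alone, and Ccnb2, a mitotic cyclin, had a value of -0.81 ± 0.25 and the kinesin gene Kif11 of -0.68 ± 0.20. The cholesterol synthesis list fell by 0.393, lower in 16 of 17 genes (camera adjusted p = 0.00119, and adjusted p = 0.358 with an estimated correlation), with -0.91 ± 0.13 for Dhcr7 and -0.83 ± 0.22 for Cyp51, both enzymes of the pathway. The p53 targets fell by 0.333 (camera adjusted p = 0.0171, and adjusted p = 0.291 with an estimated correlation) and the epithelial markers by 0.204 (0.0217, and adjusted p = 0.588 with an estimated correlation). In these 3 lists 0 members passed, and adjusted over the list alone 1, 3 and 2 genes were lower and 1 epithelial marker was higher. With the MBA-15 share matched, the epithelial list lost its call (mean -0.142, camera adjusted p = 0.136), and the cell cycle (-0.347, 2.18e-05), cholesterol (-0.422, 0.000615) and p53 (-0.385, 0.0071) lists kept theirs. With an estimated correlation these kept calls had adjusted p = 0.255, 0.484 and 0.279 there. Over all genes, the twentieths of expression in DA3 co-culture ran from a median of 0.176 in the seventh to -0.318 in the fifteenth, and after removal of that trend the mean was -0.12 for the cell cycle list, -0.121 for cholesterol synthesis, -0.124 for the p53 targets and -0.023 for the epithelial markers, at percentiles 4, 12.9, 12.3 and 44.7 of 10000 random lists of like expression. Of the 11 lists that did not pass camera in DA3, 8 lay high among such random lists, with a mean of 0.442 for the interferon response (percentile 100), 0.493 for the transition regulators (100), 0.387 for the immediate early genes (100) and 0.297 for the adhesion genes (100). The same measure was 0.251 for the unfolded protein response (99.4), 0.213 for hypoxia and glycolysis (99), 0.161 for the chemokines (98.7) and 0.182 for the NF-kB targets (98.3). With the MBA-15 share matched, the means were -0.224, -0.071, 0.217 and 0.12 for the interferon, transition, immediate early and adhesion lists. They were 0.026, -0.057, -0.091 and -0.024 for the unfolded protein, hypoxia, chemokine and NF-kB lists. Camera called none of these 8 there (adjusted p from 0.136 to 0.926). The random lists do not carry the correlation between the genes of a list. The remaining lists did not pass: interferon response (mean 0.237, camera adjusted p = 0.14), chemokines and cytokines (0.065, 0.199), transition regulators (0.263, 0.0771), TGF-beta targets (-0.061, 0.411), NF-kB targets (0.055, 0.309), hypoxia and glycolysis (0.012, 0.653), unfolded protein response (0.025, 0.763), immediate early genes (0.226, 0.23), Wnt and Notch genes (-0.041, 0.309), adhesion genes (0.179, 0.182) and endothelial markers (0.112, 0.0587). Of their members, Itga2 among the adhesion genes rose and Ccl20 among the chemokines fell, and adjusted over the list alone 2 adhesion genes, 5 transition regulators, 1 NF-kB target and 1 hypoxia gene were higher. Adjusted over the list alone, 2 chemokines, 2 Wnt and Notch genes and 1 gene in each of the transition, TGF-beta, NF-kB, hypoxia and adhesion lists were lower. The mean and the median differed in sign for the TGF-beta, hypoxia, unfolded protein, and Wnt and Notch lists.

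The third comparison set the arrays labelled MBA-15 alone against DA3 alone. The genes with the largest differences that passed were higher on the arrays labelled MBA-15 alone, among them Nrn1, or neuritin, by 4.95 ± 0.35 log2 units, Vcan by 4.84 ± 0.36, the growth factor gene Fgf7 by 4.65 ± 0.31, the chemokine gene Ccl2 by 4.32 ± 0.32 and Col1a2 by 4.22 ± 0.36 (limma, adjusted p = 0.00133, 0.00158, 0.00128, 0.00142 and 0.00256). Genes lower on them differed by little, the largest that passed being Mgat4a and Car12 at -1.31 each. The tight junction gene Cldn7 was lower by 1.15 on the arrays labelled MBA-15 alone (-1.15 ± 0.19, limma adjusted p = 0.0341) and the cadherin gene Cdh3 by 1.16 (-1.16 ± 0.19), while Epcam did not pass (-0.67 ± 0.27, adjusted p = 0.398).

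In limma 539 genes were higher and 37 lower on the arrays labelled MBA-15 alone, and 2370 genes had an unadjusted p under 0.05. Emb (4.77), Nqo1 (4.49), Trim30a (4.43), Fstl1 (4.34) and Prl2c5 (4.33) were also among the most raised that passed, and Lad1 (-1.26), the epithelial transcription factor gene Elf3 (-1.22), Chrnb1 (-1.15), Il23a (-1.13), Cldn6 (-1.12) and Arhgap8 (-1.11) among the most lowered that passed. Vcan was 4.55 higher within assay 3 and 5.12 within assay 4, and Cldn7 was -0.75 and -1.54. Without array 1 labelled MBA-15 alone, DA3 alone array 1 or DA3 alone array 2, 267, 136 and 148 genes were called. The count of lower genes, 37, was 0, 0 and 1 without these arrays, 14 without either MBA-15 co-culture array, 111 without array 2 labelled MBA-15 alone, 16 with the replicate block and 91 with median centring. With the MBA-15 co-culture arrays in place of the arrays labelled MBA-15 alone, a comparison chosen after the data were examined, 1213 genes were higher and 1290 lower than in DA3 alone, including 573 of the 576 calls.

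Interferon response genes were higher as a group on the arrays labelled MBA-15 alone than in DA3 alone, with 20 of 32 passing (29 adjusted over the list alone) and a mean difference of 2.36 (camera adjusted p = 2.17e-35, and adjusted p = 0.16 with an estimated correlation). Matrix genes were higher in 14 of 30 (18 adjusted over the list alone; mean 1.64), stromal markers in 12 of 32 (14; mean 1.30) and transition regulators in 9 of 16 (11; mean 1.73), with camera adjusted p = 2.28e-19, 2.4e-15 and 2.93e-17. With an estimated correlation the stromal markers passed (adjusted p = 0.0305), and the matrix and transition lists had adjusted p = 0.0625. The epithelial markers were lower in 5 of 32 (23 adjusted over the list alone; mean -0.869, camera adjusted p = 2.93e-17, and adjusted p = 0.16 with an estimated correlation). Chemokines (0.645), osteoblast genes (0.591), matrix proteases (0.913), NF-kB targets (0.618), hypoxia and glycolysis (0.41), cholesterol synthesis (0.425) and p53 targets (0.393) were higher as lists. Of these 7, 7, 4, 3, 4, 3, 0 and 1 members were higher and 0 lower, and adjusted over the list alone 9, 4, 10, 5, 5, 2 and 7 were higher, and 3 chemokines, 1 hypoxia gene and 2 p53 targets were lower. Their camera adjusted p was 0.0129, 0.00702, 1.99e-08, 0.00124, 0.00364, 0.00124 and 0.00124. It was 0.185, 0.223, 0.0838, 0.16, 0.223, 0.328 and 0.0864 with an estimated correlation. The other 10 of the 22 lists did not pass, with means between -0.155 for the cell cycle and 0.341 for adipocyte markers, and the mean and the median differed in sign for the TGF-beta, unfolded protein, adhesion, leukocyte, endothelial and adipocyte lists.

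The fourth comparison asked whether the co-culture difference itself differed between the lines. In limma 0 genes had a higher and 12 a lower change in MBA-15 than in DA3, and 1260 had an unadjusted p under 0.05. The keratin genes Krt18 and Krt7 differed most of these, by -3.86 ± 0.27 and -3.85 ± 0.22 (adjusted p = 0.0315 and 0.0183), followed by Cldn7 (-3.45 ± 0.27), Atp9a (-3.29 ± 0.30) and Mpzl2 (-3.25 ± 0.28). Krt18 changed by -3.71 in MBA-15 and had a value of 0.15 in DA3. Across genes, which are not independent replicates, the changes of both lines correlated with Pearson's r of 0.407 and Spearman's rho of 0.396, and r was 0.231 within assay 3. The lines had 5 called genes in common, namely Stra6, Asb2, Edn1, Ccl20 and Atp6v0e2, all lower in co-culture. All 5 were higher in DA3 alone than in MBA-15 co-culture. The levels were 7.94 and 4.18 for Stra6, 7.39 and 4.21 for Asb2, and 6.61 and 4.82 for Edn1. They were 6.46 and 3.78 for Ccl20, and 6.45 and 3.96 for Atp6v0e2. Their fall in MBA-15 therefore cannot be told apart from DA3 RNA on the arrays labelled MBA-15 alone. With the replicate or the assay number as a block 0 of the 12 genes were called, and fewer genes were called when any 1 array was left out.

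The separation of the fractions was measured on genes over 3 log2 units apart between the lines in the alone arrays of one replicate number, read against the alone array of the other number. The 124 and 80 genes higher on the arrays labelled MBA-15 alone had a median difference of 0.628 and 0.975 between DA3 co-culture and DA3 alone (0.393 and 0.54 at a distance of 2 log2 units). Between MBA-15 co-culture and the arrays labelled MBA-15 alone the median was 0.717 and 0.378. At this distance 0 genes were higher in DA3 alone, so no value could be had for DA3 genes.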

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

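All tests on Y-linked genes, on a wrong label, on the lower DA3 share, on Itga2 and its companions and on Prl2c5 were chosen only after the result was seen; the tests of the called genes and of the correlation at the higher DA3 share and of the stromal excess were set down before their results.

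The co-culture difference itself differed between the lines for 5 named genes and 9 gene lists. The genes, with the change in MBA-15 minus the change in DA3, were Krt18 (-3.86), Krt7 (-3.85), Cldn7 (-3.45), Atp9a (-3.29) and Mpzl2 (-3.25), each past an adjusted p of 0.05 in limma. With the replicate or the assay number as a block, 0 of the 12 genes called for this contrast remained. The contrast uses the arrays labelled MBA-15 alone and was not repeated with a matched share. With the DA3 share matched, the epithelial mean in MBA-15 went from -2.242 to 0.109, in part by construction. The lists past the threshold in camera with a lower change in MBA-15 were the epithelial markers (-2.037, lower in 31 of 32 genes), chemokines and cytokines (-0.329), NF-kB targets (-0.341), unfolded protein response (-0.331), immediate early genes (-0.429), adhesion genes (-0.392) and muscle and cartilage markers (-0.285). Cholesterol synthesis (0.286) and p53 targets (0.237) passed with a higher change in MBA-15. Their means were -0.107 and -0.097 in MBA-15, where they were not called, and -0.393 and -0.333 in DA3. With an estimated correlation 0 of these 9 lists passed, and their adjusted p lay between 0.324 for the epithelial markers and 0.61 for the immediate early genes.

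Epithelial genes were lower in MBA-15 co-culture, with 154 of the 169 calls lower and a correlation with the DA3 changes. A lower epithelial expression in the MBA-15 cells as the whole cause is argued against by the Y-linked Eif2s3y, Uty and Kdm5d, low in DA3: they were higher in MBA-15 co-culture by at least 3.9 standard errors each, and a DA3 array under a wrong label by the genes restricted to MBA-15, which kept a median of at least 53.1% of their co-culture level on the arrays labelled MBA-15 alone. RNA of DA3 cells on those arrays may account for the pattern, since the Y-linked genes were higher by a median of 0.8 in co-culture (1 of 3 passed the test). At the lower shares of 22.6% and 46.9% that the MBA-15-restricted genes leave, the median absolute change of the 143 called genes outside the restricted ones went from 1.94 to 0.37. This smaller change holds in part by construction. All 154 lower calls were more than 1 log2 unit higher in DA3 alone than in MBA-15 co-culture. All 15 higher calls were more than 1 log2 unit lower there, so mixing in DA3 RNA shrinks each of these changes. The epithelial markers stayed lower at the lower shares (mean -0.309, camera adjusted p = 2.06e-08). At the higher shares of 41.2% and 61%, limma called 0 of the 169 (269 genes at an unadjusted p under 0.05), but those shares were set on DA3 genes, so the match removes their fall by construction, and the correlation, 0.39 with different DA3 alone arrays on its 2 sides, was 0.124 there, under the bound of 0.2 set for DA3 RNA as its cause, and 0.319 at the lower shares, over the bound of 0.3 set against it, so its cause stays open. A response of MBA-15 to co-culture stays open beside it, since the matched comparisons called few planted changes. They called only 55 and, at the lower share, 48 of 200 planted changes of 2 log2 units and 0 of 200 of 1. Camera called 13 and 9 lists, though 0 with an estimated correlation. Called at both shares, all with negative means, were the chemokine, TGF-beta, NF-kB, hypoxia, cholesterol, unfolded protein response and immediate early lists. The NF-kB list (-0.26 and -0.229) was not called as deposited. The TGF-beta and unfolded protein lists were, the latter with matched means of -0.142 and -0.179 (camera adjusted p = 2.05e-05 and 3.79e-07). The unfolded protein list had a mean level of 7.92 in MBA-15 co-culture and 8.13 in DA3 alone. The interferon response was called at the higher share alone (-0.363 and -0.074, camera adjusted p = 1.27e-07 and 0.185). The higher share mixes in more DA3 RNA than the MBA-15-restricted genes leave, which by itself lowers lists high in MBA-15. The lower share was set on MBA-15 genes, so the small means of such lists hold in part by construction. For lists high in MBA-15, the calls therefore cannot decide between a response and the share used.

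Stromal and matrix genes were higher in DA3 co-culture by a median of 0.321 over 62 members. RNA of MBA-15 cells may account for most of the rise, since the median excess over the rise that their share predicts was 0.111 (quartiles -0.071 and 0.287). That share was set on genes high in MBA-15, which members of these lists can be. The small excess may thus hold in part by construction. A raised stromal expression in DA3 stays open, with or without MBA-15 RNA. The Y-linked Eif2s3y, Uty and Kdm5d were higher on both DA3 co-culture arrays than on both DA3 alone arrays, but by 0.42, 0.18 and 0.31, the lowest of them 0.9 standard errors, and 0 of 3 passed (limma adjusted p = 0.359, 0.662 and 0.314).

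Itga2, Cpa4, Serpinb2 and Upp1 were higher in DA3 co-culture, the first pair past the threshold. MBA-15 RNA is argued against by their levels, which were at least 0.84 log2 units higher on each DA3 co-culture array than on either MBA-15 co-culture array. RNA of leukocytes as the whole cause is argued against by the mean of 0.173 of the leukocyte markers, of which 0 passed. That list was called higher by camera, though (adjusted p = 0.0247, and 0.579 with an estimated correlation). Its mean levels of 3.95 and 4.12 lie below the array medians, so a small share of leukocyte RNA is not excluded. The assay number as the whole cause is argued against by rises of at least 2.34 within assay 3. The genes were picked for large rises on arrays that include this pair, so those rises hold in part by construction. With the assay number as a block 0 genes were called in DA3. Assay 5 holds only 1 DA3 co-culture array, so that fit rests on the other co-culture array, and its lack of calls cannot decide. A response of the carcinoma cells to co-culture, the condition the design names, is therefore a hypothesis for these 4 genes, and it was found and tested on the same data. Prl2c5 cannot be told apart from MBA-15 RNA: it would need a share of 15.9% and 35.6% on the DA3 co-culture arrays, where the 41 restricted genes, itself among them, had medians of 5.4% and 5.1%, and the highest of the 40 others stood above it on array 1 (17.7%) and below it on array 2 (24.3%).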

How the results depend on the processing

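The matched shares and the MBA-15 co-culture arrays in place of those labelled alone were chosen only after the result was seen; the other alternatives were planned. The labels do not say that the replicate numbers pair the arrays. The differences between replicates 1 and 2 correlated across genes at 0.01 between the MBA-15 groups, 0.032 between the DA3 groups and 0.135 between the groups labelled alone. They correlated at 0.311 between the co-culture groups, 0.213 between MBA-15 co-culture and DA3 alone, and -0.413 between MBA-15 alone and DA3 co-culture. In all groups but DA3 co-culture the number goes with the assay number. With the replicate block, 8 genes rose and 134 fell in MBA-15, 1 rose and 2 fell in DA3, 16 were lower between the lines alone and 0 were lower for the difference; the list calls stayed within 1.5 times. With the assay block, the counts were 5 higher in MBA-15, 0 and 0 in DA3 and 0 for the difference. With only the 4 arrays of a comparison they were 0 higher and 28 lower in MBA-15 and 0 and 0 in DA3, where fewer arrays leave fewer degrees of freedom. A repeat of quantile normalization gave 1 higher in DA3 and 29 lower for the difference, and median centring gave 11 lower in DA3 and 91 lower between the lines alone. The filter on dim genes, which tests 11060 genes, gave 8 higher and 234 lower in MBA-15, 19 and 44 in DA3, 41 lower for the difference and 5 list calls in MBA-15. The intensity trend gave 43 higher and 283 lower in MBA-15, 40 and 80 in DA3, 67 lower between the lines alone and 36 lower for the difference. A minimum of 2-fold gave 9 higher in MBA-15 and 22 lower between the lines alone. An estimated correlation left 0, 0, 1 and 0 list calls. The mean over probe sets, the random assay block and a minimum of 1.5-fold kept each count of calls within 1.5 times. With the DA3 share matched 0 genes were higher and 0 lower in MBA-15, with or without the replicate block (269 and 271 at an unadjusted p under 0.05 in limma), while camera called 13 lists, and the correlation of the lines was 0.124. With the lower DA3 share matched, 0 genes were higher and 0 lower (283 unadjusted), camera called 9 lists and the correlation was 0.319. With the MBA-15 share matched 1 gene was higher in DA3 and 6 lists were called. With MBA-15 co-culture in place of the arrays labelled alone 1213 genes were higher and 1290 lower than in DA3. At a distance of 2 log2 units the carry-over medians in DA3 were 0.393 and 0.54.

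Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave 0 to 16 genes higher and 13 to 182 lower in MBA-15, 0 to 2 and 0 to 1 in DA3, 136 to 613 and 0 to 111 between the lines alone, and 0 to 0 and 0 to 8 for the difference. List calls ran from 6 to 9, 6 to 11, 11 to 15 and 2 to 10 in the same order, and the correlation of the lines from 0.219 to 0.496. Directions reversed for the interferon list in MBA-15 (-0.046 without co-culture array 1, -0.077 to 0.855 over all arrays, the lowest without array 2 labelled alone) and the TGF-beta targets (-0.723 to 0.033, the highest without co-culture array 2). With the DA3 share matched, with and without the replicate block, they reversed for the interferon (-0.363), osteoblast (-0.066), matrix (-0.223), protease (-0.231), epithelial (0.109), stromal (-0.187), transition (-0.275) and cell cycle (0.01) lists and for Mpzl2 (0.08), S100a14 (0.19), Esrp1 (0.28) and Acox2 (0.03). With the lower DA3 share matched, the interferon (-0.074), matrix (-0.035), stromal (-0.038) and transition (-0.057) lists reversed and were not called. With the MBA-15 share matched the matrix list in DA3 reversed (-0.073). Apart from the fewer arrays or genes of some settings and the RNA mixed in for the matched ones, the cause was not tested.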

Other observations

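With an intensity trend in eBayes 40 genes were higher and 80 lower in DA3 co-culture, where the planned fit called 2 and 6; the genes named here were chosen after their values were seen. Ceruloplasmin, Cp, was at 5.94 in DA3 co-culture against 10.17 in DA3 alone (-4.23, limma adjusted p = 0.00211 with the trend and 0.0796 without it), and the lipocalin gene Lcn2 and the lactoferrin gene Ltf differed by -3.12 and -2.17 (adjusted p = 0.0209 and 0.0277 with the trend). Axin2 (-2.45), Notum (-1.91) and Ccn4 (-1.79) passed as lower with the trend (adjusted p = 0.00785, 0.0404 and 0.0198), while the fixed list of 28 Wnt and Notch genes did not pass in DA3 (mean -0.041, median 0.148, 19 of 28 higher, camera adjusted p = 0.309). The serine protease gene Tmprss2 (-2.73) and the cytokine gene Il33 (-2.54) passed as lower too (0.00121 and 0.0138). In DA3 co-culture Axin2 (3.94), Tmprss2 (4.14) and Il33 (4.06) lay below the lowest array median of 4.479. Their differences are at best lower bounds.

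Among the genes that passed as higher in DA3 co-culture with the trend were Sfn (2.27), the kallikrein gene Klk6 (1.65), the cornified envelope genes Lce1j (2.09) and Lce1h (1.64), and the laminin gene Lama3 (1.61), with adjusted p = 0.0194, 0.00211, 0.031, 0.0301 and 0.0205. Their DA3 co-culture levels of 9.50, 5.72, 7.56, 5.78 and 7.23 stood above those in MBA-15 co-culture of 4.73, 3.92, 5.67, 4.14 and 4.60. In DA3 alone Klk6 (4.07) and Lce1h (4.14) lay below the lowest array median of 4.479, so their differences are at best lower bounds. Other genes of the cornified envelope went the other way. Tgm1 (-1.74) and Ppl (-1.34) passed as lower with the trend (limma adjusted p = 0.00919 and 0.0457). The matrix protease gene Mmp10 (2.31), the prostaglandin synthase gene Ptgs2 (1.98) and Ndrg1 (1.83) passed as higher as well (0.0104, 0.0173 and 0.0278), at 7.57, 10.96 and 9.62 in DA3 co-culture against 5.27, 11.25 and 7.21 in MBA-15 co-culture. In the fit of all 19938 genes without the trend, none of the genes named in these paragraphs passed. With the filter on dim genes and no trend, Cp (0.0115), Tmprss2 (0.0132), Axin2 (0.0326), Ccn4 (0.0326), Il33 (0.0402), Sfn (0.0326), Klk6 (0.0326), Lama3 (0.0415), Tgm1 (0.0307), Mmp10 (0.0326) and Ndrg1 (0.0304) passed in limma, with the adjusted p given.

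The 13767 probe sets without a single gene name gave 0 calls in either direction in both co-culture comparisons in limma. The mean over 51 small nucleolar RNA genes was 7.31 on MBA-15 co-culture array 2 and between 5.99 and 6.71 on the other 7 arrays.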
